A study of Mus musculus with 2 samples.

How the data were processed

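Genomic DNA from the hypothalamus of female mice was compared between postnatal day 21 (P21) and the day of birth (P0) on 2 two-colour Agilent tiling arrays, called replicates A and B here. The animals were a mixture of C57BL/6J and C3H/HeJ and non-agouti, per the labels. The design text names biological replicates but gives neither the number of animals nor whether DNA was pooled, so the p-values measure the spread between these 2 arrays. In array A the red dye (Cy5) carried P0 DNA and the green dye (Cy3) P21 DNA. In array B the dyes were exchanged, per the labels.

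The assay was a methylation-specific amplification microarray. Per the design text, 500 ng of DNA was digested by SmaI and then XmaI, ligated to adaptors, amplified by PCR and cohybridised. As general background, both enzymes recognise CCCGGG. SmaI cuts it to blunt ends when it is unmethylated, and XmaI then cuts the methylated copies to sticky ends. Adaptors join the sticky ends, so a fragment is amplified when the sites at its ends were methylated. A higher P21 over P0 ratio is therefore more signal from fragments of that kind at P21. It is not a methylation percentage, and a ratio within an array shows unequal change between places, not an absolute level.

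The scanner files come from Feature Extraction 10.5.1.1, per the file headers, while the submitters' processing notes name Agilent Feature Extraction 9.1.3.1. The deposited log10 ratios are red over green processed signals after background subtraction and linear dye normalisation, per the file headers. The deposited processed intensity values are on a linear scale, with a small positive value for spots at or below background. The header statistics record spatial detrending in both arrays and multiplicative detrending in the red channel of array A alone. The deposited spot and background intensity values are medians, and the deposited flags mark spots as well above background, saturated or outlying with 0 or 1. The log10 ratio matched the processed signals to within 0.001 for 99.0% of non-control spots in array A and 98.9% in array B. The authors' processed table holds the same log10 ratios, rounded, with the sign of array A turned. Its correlation with red over green was -1.00 for array A and 1.00 for array B, and its largest difference from the turned log10 ratios was 0.00496 in either array. The median of its columns was 0 in both, so its scale, centring and direction are known.

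Each array held 96645 spots, of which 6110 were controls and 90535 were not. Control spots were left out, as were 800 spots carrying an outlier flag in either array (30 in array A and 775 in array B). No spot was saturated (0 in both arrays). Spots of 1 probe were averaged, which concerned 9 probes. The log10 ratios were multiplied by log2 of 10, turned to P21 over P0 and centred on the median of each array, giving log2 values computed here from the authors' log10 ratios. This left 89726 of 90526 probes, which are 45 to 60 nt long. No loess or quantile step was used in the main values, because methylation can shift many probes one way.

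Probes carry an identifier and a position on genome build mm8, per the file headers, and no gene name (0 probes paired with a gene). The gene table used here is on another assembly, so none of its coordinates were used and no interval was given a gene. The planned tests per gene, the planned shifts of 15 gene lists and the planned contexts based on genes and CpG islands were therefore not run. Intervals between neighbouring CCCGGG sites could not be read from a genome sequence. The fallback fixed beforehand was used, which joins probes of 1 chromosome with gaps of at most 500 bp. Of 21369 such runs, 18761 kept at least 2 probes and were tested. A run of over 4 probes can join neighbouring restriction fragments.

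Intervals and probes were tested with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with the data.table package, version 1.17.8. The test was two-sided against 0, and calls needed a Benjamini-Hochberg adjusted p under 0.05. With 2 arrays the test has 1 residual degree of freedom per interval plus the shared prior. A rule of size was therefore set beside it: a mean log2 ratio of at least 1 in size, with at least 0.585 in size in the same direction in each array. The same rule on red over green ratios, not turned, measures dye bias and chance. A correlation across probes or intervals treats them as points, not as independent replicates. Shares of intervals are given with Wilson or exact 95% intervals, which cover counting error only.

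The intervals named are the 12 higher and 12 lower with the largest mean log2 ratio among those past the adjusted threshold with the same sign in both arrays. The rule was fixed before the data were examined for intervals with a gene name, and naming them by position instead was decided afterwards. The split of intervals by probe number, the distance classes, the 1 Mb windows, the tests of X calls against autosomal calls, and the thresholds for intervals that differ between arrays were also chosen after the data were seen. Where the dimmer age was well above background at no probe of an interval on either array, a fold is a lower bound. It sets the brighter channel against the higher of the dim value and the lowest signal of probes well above background. Bounds are taken after loess and Aquantile on the processed signals, a scaling that the main values do not use.

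The calls were tested on simulated data in 18761 intervals with the noise of the P21 against P0 comparison. Of 50 intervals raised by 2 log2 units 49 were called, as were 50 of 50 lowered by 2, and 37 of 50 (74.0%) for a change of 1 in either direction. Of 18561 unchanged intervals, 3 were called higher and 3 lower. The noise was drawn from the difference between the 2 arrays, so an error that both arrays share is absent from it. These counts are therefore not the rate of false calls in the data. Alternatives were normexp background correction (offset 50) with and without loess, loess on the processed signals, no centring, the authors' processed values, filters on dim, saturated and outlying spots, other interval definitions, thresholds and limma settings, and each array alone. Because the files hold medians, normexp used median spot signals in place of means. The normexp offset is added to both channels, so it shrinks the ratios of dim spots by construction. Both arrays lay on 1 slide and were scanned together, so no batch was tested. The number of arrays limits the precision.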

Results

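The study asked how DNA methylation of the mouse hypothalamus changes over the suckling period, from P0 to P21. It hybridised P21 and P0 DNA together on 2 arrays with the dyes exchanged. Probes lay on 21 chromosomes, and 18761 intervals with a median span of 605 bp were tested, of which 9299 held 4 probes. In array A, 94.2% of non-control spots were well above background for P21 and 95.3% for P0. The corresponding shares in array B were 93.8% and 93.9%.

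Many intervals differed in the same direction on both arrays, and the largest differences were higher signal at P21. The interval on chromosome 3 from 84751599 to 84752189 (mm8, as for all positions) had a P21 signal 16.8-fold that of P0, or 10.8-fold with normexp and loess. Decreases were smaller where both ages were measured. For example, on chromosome 13 from 51539221 to 51539576 the log2 ratio was -1.61, against -1.62 with normexp and loess and -1.34 with normexp alone, where it no longer passed in limma. This interval was the brightest of the 12 lowered ones named below (mean log2 intensity 13.4) and is not typical of them. With normexp and loess, 10 of those 12 no longer passed in limma. On chromosome 2 from 103818554 to 103818862, P21 was not well above background at either probe. P0 was at least 2.45-fold higher there by the bound, which is taken after loess and Aquantile on the processed signals. Folds with normexp background correction cannot test that bound, because the offset of 50 in both channels shrinks dim ratios by construction. The interval was 1.26-fold lower at P21 with normexp and loess (limma adjusted p = 0.281) and 1.68-fold lower with normexp alone (limma adjusted p = 0.952). Its limma adjusted p ran from 6.84e-09 to 0.952 over the alternatives. Across intervals the log2 ratios of the arrays correlated with r = 0.726 (rho 0.499), and across 89726 probes with r = 0.586 (rho 0.317). Intervals and probes are not independent replicates. Before array A was turned, the interval correlation was -0.726, the same value with its sign changed by the turn and no separate result. The median absolute difference between arrays was 0.20 log2 units per interval. With normexp and no loess, the probe correlation was 0.0654.

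**Figure D1:**
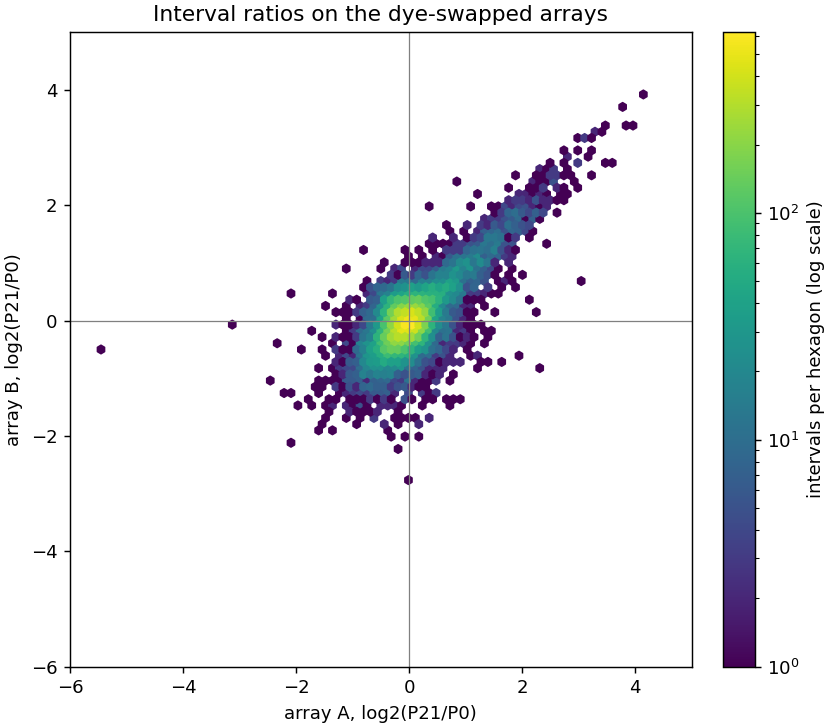
Density of 18761 intervals by their log2(P21/P0) on array A (x axis) and array B (y axis), which carry the dyes in opposite orientation, with colour giving the intervals per hexagon on a log scale. The cloud stretches along the diagonal towards values near 4 at the upper right (r = 0.726), and single intervals far below 0 on array A alone lie at the left.

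Signal was higher at P21 in 1435 intervals and lower in 749 (limma, adjusted p under 0.05), together 2184 or 11.6% of those tested. The higher intervals had a median log2 ratio of 0.98, and the lower ones of -0.70. With the 8 higher and 24 lower intervals whose dimmer age was not well above background set at their bounds, a change of at least 2-fold was reached by 692 higher and 95 lower intervals. At least 4-fold was reached by 115 higher and 0 lower intervals, and at least 8-fold by 17 and 0. In these counts the bounds are taken after loess and Aquantile, and the other folds are main values. By single probes, limma called 1882 higher and 83 lower. The probe counts moved widely with the settings, for example to 4998 and 1181 with loess on processed signals, 5115 and 1104 with trend and robust settings, and 6056 and 2061 where both channels were well above background. At an unadjusted p under 0.05 there were 4628 intervals.

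The rule of size gave 696 higher and 94 lower intervals, so that 88.1% were higher (Wilson 95% interval 85.7 to 90.2%). Of these, 695 higher and 94 lower intervals were also called by limma. The same rule applied to red over green ratios that were not turned gave 8 intervals. On array B alone, without replicate A, it gave 680 higher and 264 lower intervals. With normexp and loess the rule gave 399 higher and 8 lower intervals (98.0% higher), and with normexp alone 502 and 9 (98.2%). The normexp offset shrinks dim ratios by construction, and 564 of the 749 lower limma calls lay in the dimmer 9381 intervals. Shares with normexp, here and among limma calls, are therefore no separate test of the balance. Among limma calls the share of higher intervals was 65.7%, and it moved with the processing. It was 57.3% with trend and robust settings, 61.5% with loess on the processed signals, 76.8% with normexp and loess (1078 higher, 325 lower) and 99.3% with normexp alone (278 higher, 2 lower).

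The 12 most strongly raised intervals lay on 10 chromosomes, with log2 ratios from 3.12 to 4.07 and limma adjusted p from 0.000201 to 0.000492. The chromosome 3 interval had a log2 ratio of 4.07 ± 0.18 (SD, n = 2), with 4.20 on array A and 3.94 on array B. On chromosome 9 the interval from 96246794 to 96247461 had 3.71 ± 0.077, or 13.1-fold between P21 and P0, against 8.30-fold with normexp and loess. The interval on chromosome 7 from 108982249 to 108982823 had 3.65 ± 0.40, and that on chromosome 17 from 14430390 to 14430811 had 3.62 ± 0.28. Chromosome 2 held 3 of the 12. Their log2 ratios were 3.40 ± 0.078 at 60353846 to 60354482, 3.24 ± 0.042 at 33258736 to 33259377, and 3.18 ± 0.076 at 33522835 to 33523458. The remaining members lay on chromosome 15 from 102846563 to 102847189 (3.31), chromosome 4 from 55229725 to 55230150 (3.28), chromosome 5 from 135538166 to 135539070 (3.16), chromosome 12 from 109885926 to 109886570 (3.15) and chromosome 1 from 133799084 to 133799923 (3.12). Of these, the chromosome 12 interval had the widest spread, with 3.61 on array A and 2.70 on array B. All probes of all 12 intervals were higher at P21 on both arrays. With normexp and loess their log2 ratios ran from 2.23 to 3.44, and the fold of 5 of the 12 moved by over 1.5 times, most for the chromosome 4 interval (log2 ratio 3.28 to 2.23) and the chromosome 15 interval (3.31 to 2.32).

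Of the 12 lowered intervals named, 1 is the chromosome 2 interval with P21 below background, which has a bound in place of a fold. The others had log2 ratios from -1.77 to -1.54, smaller in size than those of the raised intervals, and limma adjusted p from 0.000821 to 0.0115. The X interval from 92202434 to 92202712 was at -1.77 ± 0.95 (SD, n = 2), with -2.44 on array A and -1.09 on array B. On chromosome 18 the interval from 77760887 to 77761390 had -1.74 ± 0.73. Chromosome 10 held 2 of them, at 93950009 to 93950543 (-1.70 ± 0.38) and at 30499838 to 30500482 (-1.70 ± 0.57). The interval on chromosome 9 from 98761266 to 98761651 had -1.74 ± 0.26, with P21 not well above background at 1 of its 2 probes. Chromosome 11 from 98626325 to 98626653 gave -1.65, chromosome 8 from 73114781 to 73115099 gave -1.61, and chromosome 13 from 51539221 to 51539576 gave -1.61. The remaining lowered intervals were chromosome 2 from 155891482 to 155891679 (-1.59), chromosome 16 from 10211837 to 10212392 (-1.56) and chromosome 15 from 98694133 to 98695522 (-1.54). The lowered intervals had a median log2 intensity of 7.17, against 11.6 for the raised ones. Of the 12 lowered intervals 6 held 2 probes, against 0 of the raised ones. The X, chromosome 8 and chromosome 9 intervals kept fewer than 2 probes where both channels of both arrays had to be well above background. With normexp and loess, 10 of the 12 lowered intervals no longer passed in limma (adjusted p up to 0.281), and with normexp alone none did (0 of 12), while all 12 raised ones passed in both. Apart from the interval with P21 below background, the log2 ratios of the lowered intervals then ran from -1.62 to -0.35 with normexp and loess. The normexp offset of 50 shrinks the ratios of dim intervals by construction. The contrast with the raised intervals therefore cannot decide whether the decreases are less real. The bright chromosome 13 interval (mean log2 intensity 13.4) was at -1.62 with normexp and loess and at -1.34 with normexp alone. Over the alternatives the adjusted p of lowered intervals ran from 8.89e-11 to 0.952.

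**Figure D2:**
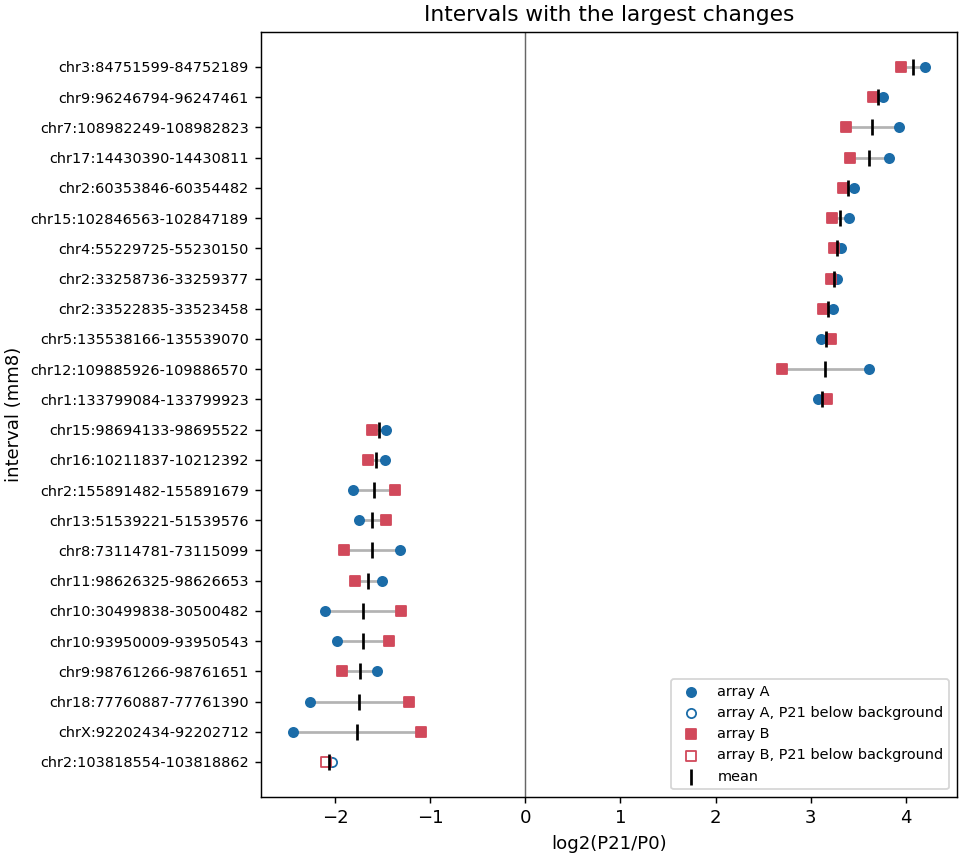
log2(P21/P0) of the 12 raised and 12 lowered intervals on array A (circles), array B (squares) and as their mean (bars), with mm8 positions on the y axis. Raised intervals have means from 3.12 to 4.07. Lowered ones have means from -1.77 to -1.54, apart from the chromosome 2 interval with open symbols. The P21 signal of that interval was below background, so that its position on the axis is not a measured size.

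Calls in the 2 directions came from different ranges of brightness. In the brighter 9380 intervals 887 were called higher and 185 lower. In the dimmer 9381 the counts were 548 and 564. The correlation between arrays was 0.403 in the dimmest of 10 classes of equal size, 0.920 in class 8 and 0.596 in the brightest.

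The X chromosome had few intervals with higher signal at P21. Of 385 X intervals 6 were called higher, which is 1.56% (exact 95% interval 0.574 to 3.36%), against 1429 of 18367 autosomal intervals, or 7.78% (two-sided Fisher's exact test, p = 1.64e-07, Benjamini-Hochberg adjusted p = 6.57e-07 over 4 comparisons). Of the 6, 5 lay together within 154799 bp, from 11157413 to 11312211, where 12 intervals were tested and 1 was called lower. Their log2 ratios ran from 0.58 to 1.48 with limma adjusted p from 0.000885 to 0.0325. In the other 373 X intervals 1 was called higher. Calls of lower signal did not separate X from autosomes, with 10 X intervals (2.60%) against 739 autosomal ones (4.02%, Fisher's exact test, p = 0.187). The mean log2 ratio of X probes minus autosomal probes was -0.12 on array A and -0.19 on array B (mean -0.15 ± 0.048, SD, n = 2). No p is given for 2 arrays. The shift was -0.10 ± 0.0074 with normexp and loess. With normexp alone it was -0.033 ± 0.125, with -0.12 on array A and 0.06 on array B, so that the arrays differed in sign. Neighbouring intervals are not independent, so the Fisher p is too small to an unknown degree.

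Among autosomes the share of intervals called higher ran from 5.19% on chromosome 18 to 10.1% on chromosome 8. Chromosome 10 was the autosome with as many lower as higher calls, 53 and 52. Chromosome 2 had 144 higher and 64 lower intervals, and chromosome 12 had 66 and 15.

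**Figure D3:**
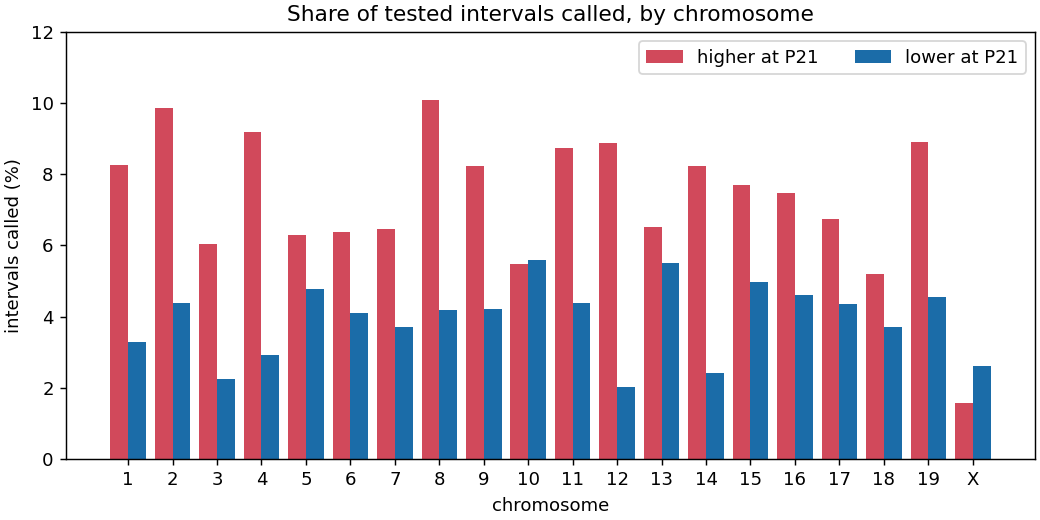
Percent of tested intervals called higher (red) or lower (blue) at P21 by limma for each autosome and X, from the mean of 2 arrays. The X chromosome has the lowest share of higher calls, 1.56%, and chromosome 8 the highest, 10.1%.

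Longer runs of probes had more signal at P21 than short ones. In runs of over 4 probes the mean log2 ratio exceeded that in runs of 2 to 4 probes by 0.05 on array A and 0.12 on array B (mean 0.09 ± 0.051, SD, n = 2). Of intervals with 2 probes 4.26% were called higher and 8.59% lower. In those with over 8 probes the shares were 11.2% and 0.518%. With normexp and loess the difference was smaller, 0.034 on array A and 0.040 on array B. With normexp alone it was 0.03 on array A and -0.03 on array B.

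The likeness of the ratios was lost with distance. Probes 60 to 100 bp apart had mean log2 ratios correlated with r = 0.889 across 15664 pairs. The value was 0.604 at 500 to 750 bp, 0.232 at 1500 to 2000 bp and 0.0283 at 10000 to 20000 bp. When array A was read at 1 probe and array B at the other, r was 0.566 at 60 to 100 bp and 0.174 at 1500 to 2000 bp. Pairs share probes and are not independent. Probes on 1 restriction fragment report the same amplified fragment, so likeness at short distance is partly built in. The r of the mean can also hold error that neighbouring probes share within an array.

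**Figure D4:**
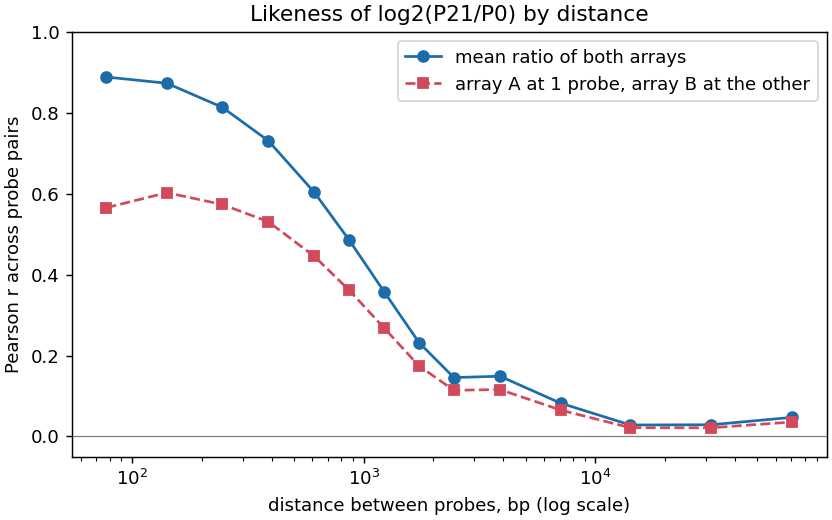
Pearson r of log2(P21/P0) across probe pairs against the distance between them in bp on a log axis, for the mean of both arrays (circles) and for array A at 1 probe with array B at the other (squares). The mean's r drops from 0.889 at 60 to 100 bp to 0.232 at 1500 to 2000 bp.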

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

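The tests for dye bias, for array medians off the bulk of the intervals, for span and for the intensity of X intervals were written after the results they concern had been seen. The test against the spread of medians, that of a uniform X shift and both tests on intervals that differ between arrays were written beforehand. Y-chromosome probes, outside the comparison of female animals, gave signal: 9 of 34 were well above background in both channels of both arrays (26.5%), against 61 of 1196 negative control spots (5.10%) and 92.2% of autosomal probes. Most of the 9 had more signal for P0 than for P21. The mean log2 ratio of Y probes was -0.45 on array A and 0.11 on array B, so the arrays differed in sign.

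More intervals were higher than lower at P21, 696 against 94 by the rule of size. Dye bias would repeat in ratios that are not turned, where 8 intervals met the rule. Centring each array on its mode left 773 higher and 70 lower, which argues against medians lying off the bulk. The share higher rose with span from 76.5 to 91.8 and 92.6% over 3 classes, and limma calls turned over with probe number (4.26% higher and 8.59% lower at 2 probes, 11.2 and 0.518% at over 8), so amplification that depends on fragment length stays open, as span is not fragment length. A constant of 0.31 log2 units would balance the counts and exceeded the 0.053 spread of medians over normalisations by the margin written for exclusion, but each normalisation fixes the median near 0, so a shared change of most of the genome cannot be told apart from wrong centring, and development from P0 to P21, including a change in cell types, stays open and untested.

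Fewer X intervals were called higher than autosomal ones, 6 of 385. Autosomal sets of the same intensity had a median of 32 (95% range 22 to 42 over 10000 sets), so intensity does not account for it. Setting the X median to the autosomal median in each array left 7 called higher, still below that range. This argues against a shift shared equally by all X intervals. A different sex mix need not act equally on all of them, so the test cannot decide on it and it stays open. Correlation between arrays was lower on X than on autosomes, 0.433 against 0.729. A developmental difference between X and autosomes in females stays open and was not tested.

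Some intervals differed between arrays: 13 differed by at least 1.5 log2 units at a mean log2 intensity above 8, and 62 at any intensity. The largest lay on chromosome 7 from 139244339 to 139244617 (-5.50 on array A, -0.52 on array B) and on chromosome 8 from 13287499 to 13288451 (-3.11 and -0.06, 8 probes). On the chromosome 7 interval the P21 log2 intensity was 4.44 on array A, against 9.92 on array B. This is near the 4.19 of the named chromosome 2 interval with P21 below background, so -5.50 is not a well measured size. Single bad spots would leave most probes alike, but 92.6% of the 54 probes differed by at least 1 in the direction of their interval. Intervals were listed by the mean over these same probes, which favours intervals whose probes all differ. The share therefore describes the listed intervals only. A sequence difference at a recognition site between mixed-strain animals may leave 1 channel apart from the others, which held in 4 of the 13, too few to decide. It stays open beside differences between individual animals and a dye effect. A dye effect would give opposite signs on the 2 turned arrays. This held on chromosome 13 from 65761234 to 65761582 (-1.06 on array A, 0.87 on array B). It also held on chromosome 2 from 130851204 to 130851817 (1.67 and -0.67). The chromosome 7 and chromosome 8 intervals above had the same sign on both arrays. A dye effect in the listed intervals was not tested.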

How the results depend on the processing

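The alternatives that ask for signal well above background in both channels, gaps of at most 250 bp, runs of 2 to 4 probes, or autosomes alone were chosen after seeing the data, and the others beforehand. No mean value or balance of calls changed sign in any alternative run, though with normexp alone the 2 arrays differed in sign for the X shift and for the difference by run length. Fewer X than autosomal intervals were called higher in all 17 alternatives tested. The 12 raised intervals passed in limma in 144 of 144 values (adjusted p 4.93e-21 to 0.0139), and the lowered ones in 111 of 134. All were chosen as the largest calls on these same arrays, so passing again is weak evidence of stability. Their sizes did move: the fold changed by over 1.5 times in 5 raised and 10 lowered intervals with normexp and loess, in 2 and 5 with normexp alone, and in 0 with the other alternatives that keep both arrays. On single arrays it did so in 1, the lowered X interval, at -1.77 with both, -1.09 without replicate A and -2.44 without replicate B. No centring and leaving out saturated probes changed practically nothing, since medians were already 0 and no spot was saturated, so neither shows stability. The authors' processed values, which are the same ratios rounded, gave 2189 intervals. Causes of the changes below were not tested unless a filter or threshold itself sets them. The normexp offset shrinks dim ratios by construction, but its share of the changes was not measured. Normexp and loess gave a probe correlation of 0.678, 1403 intervals (325 lower, 76.8% higher), 200 lower probes, 407 intervals by size (399 higher, 8 lower, 98.0% higher) and an X shift of -0.10. Normexp alone gave 0.0654, 280 intervals (278 higher, 2 lower, 99.3% higher), 5 lower probes, 511 by size (9 lower, 98.2% higher), a difference by run length of 0.0032 and an X shift of -0.033. Loess on processed signals gave 0.608, 61.5% higher, and 6179 probes (4998 higher, 1181 lower). Signal well above background in 1 channel gave 0.630, 1169 lower intervals, 59.2% higher, and 7797 probes (5813 and 1984). In both channels, it gave 0.646, 1175 lower intervals, 59.7% higher, and 8117 probes (6056 and 2061). Trend and robust settings gave 3379 intervals (1444 lower, 57.3% higher) and 6219 probes (5115 and 1104). An adjusted p under 0.1 gave 1327 lower intervals, 57.4% higher, and 4511 probes (3899 and 612). A fold filter added to the adjusted p gave 68.3% higher. At least 3 probes gave 55 lower by size, 92.1% higher. Medians over probes gave 1251 intervals (261 lower, 79.1% higher). Gaps up to 1000 bp gave 50 lower by size, 92.6% higher, and gaps up to 250 bp 70.3% higher among limma calls. The smaller size gave 2041 (1358 higher, 683 lower, 66.5% higher) and the larger 116 (115 and 1, 99.1%), where the 1 is the chromosome 2 interval with P21 below background. Runs of 2 to 4 probes gave 949 higher intervals and 85.4% higher by size. With 1 array left there is no residual degree of freedom, so no test was run and no correlation exists. By size, single arrays gave 122 to 264 lower intervals and 72.0 to 86.5% higher. Without replicate A it was 264 lower and 72.0%. No paired analysis was possible because each array compares both ages directly and there is 1 group. The alternatives set down for genes and gene lists were not run, since no probe carries a gene name. Signal below background limits the fold of 24 lower and 8 higher called intervals to a bound. Of 749 lower calls, 564 lay in the dimmer 9381 intervals. Asking for both channels well above background gave more lower calls, but higher calls rose too, from 1435 to 1738. By size it gave 80 lower intervals in place of 94. The 8 named lowered intervals that could still be tested passed, with ratios that the filter left unchanged. The filter therefore cannot decide how far lower calls depend on dim signal.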

Other observations

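The windows and distance classes below were chosen after the data were seen. Called intervals lay near others of the same direction. Among 1955 pairs of neighbouring intervals 500 to 2000 bp apart, 47 were both higher where 7.79 would be expected from the calls alone, 31 were both lower against 10.02, and 4 were opposite against 17.8. At 2000 to 20000 bp, 65 of 4621 pairs were both higher against 42.0, and 8 were both lower against 6.87. Neighbouring intervals can share a restriction fragment, and no test was run on these counts.

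Of 1235 windows of 1 Mb with at least 5 intervals, 2 passed for an excess of higher calls (one-sided binomial over intervals that are not independent, Benjamini-Hochberg adjusted p under 0.05), while others lay above their expected count without passing. On chromosome 5 from 118000001 to 119000000, 10 of 24 intervals were called higher, where 1.84 were expected (Benjamini-Hochberg adjusted p = 0.00608). On chromosome 8 from 123000001 to 124000000 it was 13 of 44, where 3.37 were expected (adjusted p = 0.0102), with 1 interval lower. With normexp and loess the counts of higher intervals were 4 and 11, and with normexp alone 1 and 5. No window passed for lower calls (0 of 1235). The window on chromosome 17 from 24000001 to 25000000 had the lowest p for lower calls, 6 of 25 against an expected 0.998 (binomial p = 0.000372, which did not pass adjustment).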
